A study of Homo sapiens with 6 samples.

How the data were processed

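Total RNA from 6 human samples was measured on 6 Agilent 1-colour microarrays, 1 array per group. Per the labels' protocols, dermal fibroblasts were transduced with retroviruses for GFP alone or for combinations of the transcription factors OCT4, SOX2, KLF4 and MYC and the protein LIN-41. They were kept in medium with 10% serum to day 7 and in embryonic stem cell medium with 4 ng/mL bFGF from day 8, and were collected on day 11. OSK stands for OCT4, SOX2 and KLF4, and OSKM for the same factors with MYC. Cells of the OSK arms with an inhibitor were transfected on days 1 and 6 with an inhibitor of the microRNA let-7 or with a control inhibitor. Per the labels, the 4 reprogramming samples were cells positive for TRA-1-60, a surface epitope used to enrich cells on the way to pluripotency, and the fibroblast sample was the GFP-positive fraction. The H1 sample is an established human embryonic stem cell line.

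The scanner files hold spot intensity values made by Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09 for array design 028004, per the file headers. The processed intensity is the Cy3 brightness after background correction within the array and is not scaled between arrays. A whole-series table deposited by the authors holds log2 values. Set against the scanner files it was found to be shifted to each array's 75th percentile and centred on each probe's median over the 6 arrays, at a correlation across probes of at least 0.999998 and slopes of 0.9999 to 1.0002, so its scale, centring and direction were settled from the values. Its column medians were 0.15 for the fibroblasts, -0.08 for the OSK control, -0.02 for the let-7 inhibitor, 0.10 for OSKM, -0.02 for LIN-41 and -0.02 for H1.

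Here the log2 of the processed intensity was taken, and each array's 75th percentile over its probes was subtracted. Spots of 1 probe were averaged after leaving out control spots and spots marked as non-uniform or population outliers. No spot was saturated. A probe counted as well above background when most of its spots carried that mark. The scanner files give a probe name and an accession, and gene symbols were taken from the RefSeq table of assembly GRCh38.p14 by accession without its version. Of 42405 probes, 26364 matched 1 gene, 0 matched several and 16041 had no match and were not used for genes. The files name an older genome build, so no coordinates are given. After Y-linked genes and the X-inactivation transcripts were left out, 26256 probes of 19728 genes remained, and a gene was represented by its probe with the highest mean signal over the 6 arrays. Several probes were present for 5129 genes.

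The arrays had 75th percentile signals of 240 to 386 intensity units, and between 66.2% and 75.4% of genes were well above background. The median SD between repeated spots of 1 probe was 0.064 to 0.076 on the log2 scale. That is the precision of the spots alone. There were no replicates of any group, so no p-value was computed, no value has an error over cultures, and a difference describes a pair of arrays and not the conditions. The number of arrays limits the precision.

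Arrays lay in pairs on 3 slides scanned on 2 days, per the file headers. The OSK control and let-7 inhibitor shared a slide, OSKM and LIN-41 shared another that was scanned on the other day, and the fibroblasts and H1 shared the remaining slide. These 3 contrasts are therefore within a slide. In every other contrast the slide and the group cannot be told apart. The labels give an inhibitor transfection for the OSK control and the let-7 inhibitor only. LIN-41, OSKM and the fibroblasts therefore also differ from them by that transfection.

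For each comparison the log2 difference was taken per gene. Where only 1 side was well above background, the dim side was set at the higher of its own value and the array's lowest signal well above background, and the fold is given as "at least". Genes dim on both arrays have no fold. Genes at least 2-fold apart were counted. Before the data were examined, 19 gene lists were written, covering pluripotency, fibroblast, epithelial, let-7 target, reported LIN-41 target, immediate-early, mesendoderm, neural, trophoblast, cell-cycle, CDK inhibitor and p53, MYC and ribosome, interferon, TGF-beta, stress, keratinocyte, melanocyte, endothelial and blood genes. Of their 392 symbols, 3 were not matched and 8 were matched through an older symbol. Each list's median difference was placed among 10000 random lists of the same size matched on mean signal in 20 bins. This percentile describes the 2 arrays and is not a test. It is given for lists with at least 5 members compared. The position of a TRA-1-60 positive array between fibroblasts (0%) and H1 (100%) was the median over genes at least 4-fold apart between those, with a 95% binomial interval over genes, which are not replicates.

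Genes are named by a rule fixed at the same stage. For comparisons between cocktails it takes the 6 highest and 6 lowest genes with a symbol of their own, well above background on both arrays and at least 2-fold apart in the same direction after normexp correction too. For comparisons with fibroblasts it takes the 6 genes per direction with the largest smallest difference over the 4 TRA-1-60 positive arrays. Up to 4 members of each list at least 2-fold apart are added, and 12 genes are named whatever their value (POU5F1, SOX2, KLF4, MYC, TRIM71, NANOG, LIN28A, LIN28B, HMGA2, EGR1, PODXL and CDH1). Not all genes taken by this rule are reported here. Where probes sit relative to the retroviral coding sequences was not known here, so the probes of the transduced genes do not check the transgenes.

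Alternatives were normexp background correction (offset 50) with quantile normalization, scaling by the array median, quantile normalization alone, the 75th percentile of probes well above background on all arrays, scaling by 8 spike-in probes, the deposited log2 table, other filters on dim probes, the mean of a gene's probes, a 4-fold threshold and end-point genes at least 8-fold apart. The spot mean signal was not used here, so normexp ran on the median spot and background intensity. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1. Tested on simulated data for the let-7 comparison, with spot noise only and 14635 genes, the 2-fold count found 50 of 50 genes set 3-fold higher, 50 of 50 set 4-fold higher, 49 of 50 set 3-fold lower and 2 of 50 set 1.5-fold higher, with 31 of 14435 unchanged genes. Of 100 random lists of 20 genes, 5 lay outside the central 95% with no shift, and all 100 did with a shift of 0.3.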

Results

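Gene expression was compared on day 11 of reprogramming between human dermal fibroblasts given different factor cocktails. The 6 arrays, without replicates, were fibroblasts with GFP, TRA-1-60 positive cells from OSK with a control inhibitor (the OSK control), from OSK with a let-7 inhibitor, from OSK with LIN-41 and from OSKM, and the embryonic stem cell line H1. Let-7 is a microRNA family of differentiated cells, and LIN-41, encoded by TRIM71, is an RNA-binding protein whose transcript is a let-7 target. The comparisons ask how the TRA-1-60 positive cells differ from their starting fibroblasts and from stem cells. They also ask what a let-7 inhibitor, LIN-41 or MYC adds to OSK. Per the labels the LIN-41 and OSKM samples had no inhibitor transfection, so their contrasts with the OSK control also hold that difference. Between 13063 genes on the fibroblast array and 14869 on the H1 array were well above background. Differences are log2 values relative to each array's 75th percentile unless given as folds.

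H1 cells and fibroblasts, the 2 end points, differed at least 2-fold at 8065 of 15547 genes, with 4260 higher and 3805 lower in H1. Which direction held more genes depended on the processing. The counts were 7535 and 2028 with spike-in scaling, 3560 and 4503 with the array median, and 2892 and 3139 with genes well above background on both arrays. All 39 pluripotency genes could be compared, and their median was 7.13 higher in H1 (percentile 100 of random lists). Among them CD24 was at least 3644-fold, L1TD1 at least 2145-fold and CRIPTO, a Nodal co-receptor, at least 1319-fold higher, and DNMT3B, a DNA methyltransferase, 859.8-fold. Of 38 fibroblast genes, 37 were at least 2-fold lower in H1. LUM, a collagen-binding proteoglycan, was at least 1277-fold lower, and LOX, which cross-links collagen, 766-fold. The epithelial list was higher by a median of 4.92 and the cell-cycle list by 2.54, while the TGF-beta list was lower by a median of -1.60 and the interferon list of -3.53. The trophoblast list was lower (median -2.41, 6 genes compared), led by PSG1 at least 93.4-fold, whose gene family consists of near-identical copies, so its probe is uncertain. The melanocyte and blood lists, with 5 members compared each, lay at percentiles 43.1 and 26.4. Single members stood out, with PMEL at least 226-fold higher and CD68 at least 213-fold lower in H1.

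The 4 TRA-1-60 positive populations shared a large difference from fibroblasts, with 1904 genes at least 2-fold higher and 1781 at least 2-fold lower on all 4 arrays. NANOG, a core pluripotency transcription factor, was 197-fold higher in the OSK control, 267-fold with the let-7 inhibitor, 534-fold with LIN-41 and 256-fold in OSKM, beside 321-fold in H1. L1TD1 was at least 649-fold higher on every TRA-1-60 positive array. The pluripotency list was higher by a median of 4.11 in the OSK control, 4.28 with the let-7 inhibitor, 5.03 with LIN-41 and 5.01 in OSKM. PODXL, whose protein carries the TRA-1-60 epitope and was thus part of the sort, was 30.4- to 49.5-fold higher.

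Several strong pluripotency genes remained low in these cells. SOX2 was not well above background in the OSK control, with the let-7 inhibitor or in OSKM, and with LIN-41 it was at least 3.73-fold above fibroblasts, against at least 688-fold in H1. LIN28B, which blocks let-7 maturation, was not well above background in the OSK control or with the let-7 inhibitor, and was at least 10.0-fold above fibroblasts with LIN-41 and at least 4.70-fold in OSKM, against at least 473-fold in H1. LIN28A ranged from at least 6.66-fold in the OSK control to at least 34.0-fold with LIN-41. Where the SOX2 probe lies relative to the retroviral sequence was not known, so whether it reads the transgene could not be told.

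Epithelial genes were higher than in fibroblasts on all 4 arrays. The list medians were 2.05 in the OSK control, 1.84 with the let-7 inhibitor, 3.27 with LIN-41 and 3.51 in OSKM. With normexp those of LIN-41 and OSKM were 1.94 and 1.86. EPCAM, an epithelial adhesion molecule, was at least 46.1- to 141-fold higher, CLDN4, a tight-junction protein, 100.4- to 177-fold, and CDH1, which encodes E-cadherin, at least 15.6- to 62.3-fold. Cell-cycle genes were higher too (medians 1.68, 1.27, 1.65 and 1.47 in the same order), and all 27 lay above 0 on each array. PLK1, a mitotic kinase, was 5.35- to 8.48-fold higher, and 0.84 to 1.47 on its other probe. The leading genes by rule were IGF2, a fetal growth factor, higher by 11.81 to 13.13, then F11R, TNNT1, RNASE1, SFN and NANOG.

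Fibroblast genes were lower on all 4 arrays, with list medians of -2.87, -2.57, -2.46 and -2.96, and 29 to 32 of 38 members at least 2-fold lower. DCN, a matrix proteoglycan, was 126- to 597-fold lower, LUM 77.8- to 247-fold, and THBS1, a matrix glycoprotein, 79.1- to 206-fold. SPOCD1, TNFRSF11B and PSG5 were also among the lowest. The interferon list was lower with medians of -2.09, -2.30, -2.48 and -2.30, although USP18, an interferon-induced protease, was 17.2- to 27.3-fold higher. The TGF-beta list was lower by medians of -1.33, -0.68, -0.98 and -1.63. Immediate-early genes, which serum and stress induce within minutes, were lower by -1.44, -1.32, -1.75 and -1.49. The stress list had medians of -0.83, -0.99, -0.80 and -0.94, with HMOX1, the heme oxygenase, 4.53- to 18.8-fold lower. With spike-in scaling the stress median of LIN-41 was -0.09.

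Markers of other cell types also separated these arrays from fibroblasts. The endothelial list was higher (medians 2.30, 1.76, 3.04 and 2.12), with TEK, the angiopoietin receptor, 64.5- to 194-fold and CLDN5 at least 27.0- to 51.2-fold higher. KRT6A, a keratin of stratified epithelium, was at least 164- to 591-fold higher, though the keratinocyte list as a whole lay between percentiles 41.9 and 96.6. HAND1 was at least 24.0- to 62.6-fold higher, and MAP2, a neuronal microtubule protein, 15.3- to 69.9-fold. The mesendoderm list had medians of 0.83, 0.72, 2.11 and 2.10. The neural list had medians of 1.20, 1.47, 1.45 and 0.83 over 6 or 7 genes, and those of the OSK control and the let-7 inhibitor lay below 0 with no filter on dim genes (-0.41 and -0.28).

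**Figure D1:**
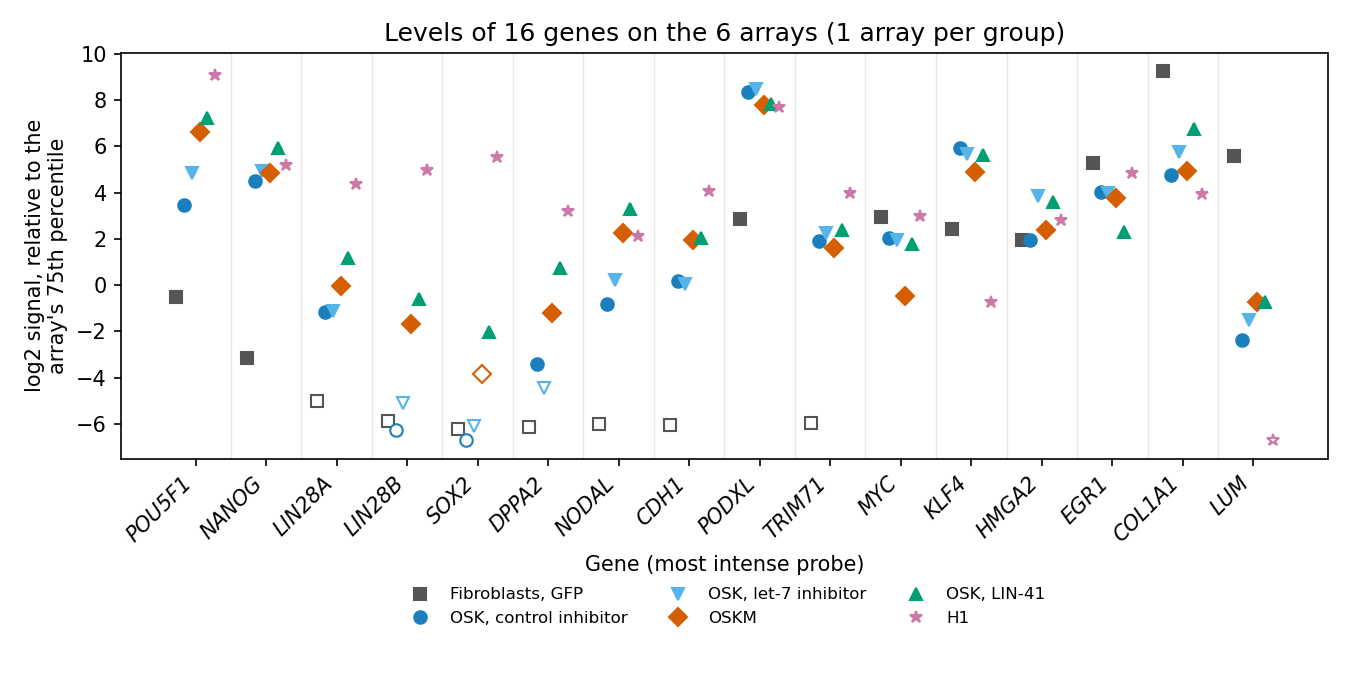
Log2 signal of 16 genes, relative to the array's 75th percentile, on the 6 arrays, with 1 marker per array and open markers for genes not well above background. SOX2 and LIN28B stay low in the TRA-1-60 positive cells while NANOG lies at 4.49 to 5.93 beside 5.19 in H1, and the fibroblast genes COL1A1 and LUM are highest in the fibroblasts.

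As a position between the end points, the 1964 genes at least 4-fold higher in H1 had gone a median of 43.6% of the way in the OSK control (95% interval over genes 39.2 to 46.0), 40.2% with the let-7 inhibitor (36.3 to 42.5), 51.4% in OSKM (49.3 to 53.4) and 55.2% with LIN-41 (52.95 to 57.2). The 1857 fibroblast-high genes had gone 54.2%, 52.5%, 57.5% and 54.1% in the same order. In the H1-high set 55.4% of genes in the OSK control, 53.5% with the let-7 inhibitor, 65.4% in OSKM and 65.8% with LIN-41 were at least 2-fold from fibroblasts toward H1. The order of the cocktails on the H1-high genes, let-7 inhibitor, OSK control, OSKM and LIN-41, was the same under each alternative. On the fibroblast-high genes it was not.

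**Figure D2:**
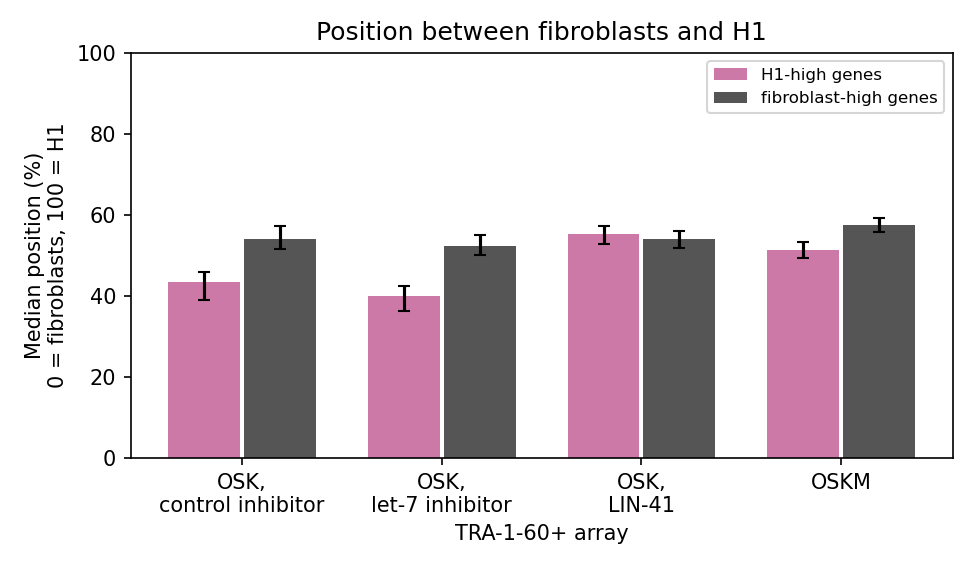
Median position of each TRA-1-60 positive array between fibroblasts (0%) and H1 (100%), for 1964 H1-high and 1857 fibroblast-high genes, with bars for the median and whiskers for its 95% interval over genes. On H1-high genes OSKM (51.4%) and LIN-41 (55.2%) lie above the OSK control (43.6%), from which they also differ by slide and inhibitor transfection.

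The let-7 inhibitor gave the smallest difference from its control, on the same slide. Of 14079 genes, 182 were at least 2-fold higher and 225 lower (116 and 334 with spike-in scaling, 49 and 55 with normexp). Of these 407 genes, 165 rested on a detection bound. Among 69 genes with several detected probes and a 2-fold one, 17 had probes of opposite sign. That is 24.6%, against 11.2% to 14.6% in the other comparisons. The leading higher genes were LEFTY2, a feedback inhibitor of Nodal signalling (5.29-fold), SWT1 (4.76-fold), ALKAL2 (4.17-fold), SORBS2 (4.15-fold), CXCL14 (4.06-fold) and COL10A1 (4.06-fold). LEFTY1 was 3.32-fold and NODAL 2.03-fold higher. The leading lower genes were FAM151A (8.37-fold), GK5 (6.14-fold), TCF15 (5.69-fold), IL22RA1 (4.81-fold), MAOA, a monoamine oxidase (4.79-fold), and GFRA1 (4.74-fold, though its other probe read -0.57). GK5 lay at -0.80 on the OSK control and at -3.24 to -4.09 on every other array, fibroblasts and H1 included. SWT1 lay at -0.63 with the let-7 inhibitor and at -2.88 to -3.35 on every other array. Each of these differences thus rests on a high reading of a single array.

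The let-7 target list as a whole had a median of 0.05 over 36 genes (percentile 86.9), which turned to -0.12 with spike-in scaling. Only HMGA2, a chromatin protein and a classic let-7 target, was at least 2-fold higher (3.64-fold). Its 3 probes disagreed, at 1.86 for the probe assigned to transcript NM_003483 and 0.19 and 0.18 for those assigned to NM_003484. TRIM71 differed by 0.35, MYC by -0.11 and LIN28A by 0.04, which turned to -0.13 with spike-in scaling.

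With the let-7 inhibitor the pluripotency list was at a median of 0.04 (percentile 90.5), turning below 0 with spike-in scaling, with 4 of 30 genes at least 2-fold higher and 0 lower. POU5F1, which encodes OCT4, was 2.58-fold higher on the probe used, which was the brighter over all 6 arrays, but read -0.24 on the other, which was the brighter on these arrays. Epithelial genes were lower, with a median of -0.49 and 3 of 24 members above 0, and RAB25 (2.80-fold) and KRT19 (2.43-fold) were the lowest. RAB25 was dim and differed by only -0.55 with normexp. KRT19 was higher in the fibroblasts (7.80) than in the OSK control (5.16), so its difference is not one toward fibroblasts. CDH1 differed by -0.13. Cell-cycle genes were lower by a median of -0.46, with 0 of 27 above 0. The MYC and ribosome list was lower by -0.17 and the stress list by -0.16 (-0.34 and -0.33 with spike-in scaling). All 3 of the fibroblast, TGF-beta and CDK inhibitor and p53 lists were higher, by 0.31, 0.52 and 0.26, at percentile 100, though the CDK inhibitor and p53 list only by 0.0904 with spike-in scaling. TGFB2 and INHBA, ligands of that pathway, were 2.49- and 2.31-fold higher, and SNAI2, a transcription factor of mesenchymal cells, 2.11-fold. Immediate-early genes were higher by 0.29, with EGR1 at -0.02. Mesendoderm genes were higher by 0.46, with LHX1 3.09-fold higher and GATA6 2.39-fold lower. Reported LIN-41 targets lay at 0.10 (percentile 94.8), which turned below 0 with spike-in scaling.

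LIN-41 with OSK was compared with the OSK control across slides. Of 14281 genes, 1025 were at least 2-fold higher and 634 lower. Both counts depended on the processing, at 3708 and 219 with spike-in scaling and 439 and 286 with normexp. The leading higher genes were ACTA1, skeletal muscle actin (59.4-fold), SP5, a Wnt-responsive transcription factor (33.9-fold), ACTG2 (22.5-fold), ZSCAN10 (18.2-fold), CNN1, smooth muscle calponin (18.04-fold), and DPPA2 (17.8-fold). TRIM71 itself was 1.38-fold higher, on a probe that need not read the retroviral transcript.

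The pluripotency list was higher by a median of 1.46 with LIN-41 (percentile 100; 2.08 with spike-in scaling), with 22 of 38 genes at least 2-fold higher and 0 lower. NODAL was 17.1-fold, LIN28B at least 13.7-fold, SOX2 at least 5.10-fold, LIN28A 5.10-fold and NANOG 2.71-fold higher. POU5F1 was 13.6-fold higher on the probe used and -0.43 on the other. The let-7 target list was higher by 0.32, or 0.93 with spike-in scaling, with HMGA2 at 1.60 on one probe and 0.46 and -0.34 on the others. Epithelial genes were higher by 0.94 (1.55 with spike-in scaling), including CDH3 (14.7-fold), CLDN6 (7.21-fold) and CDH1 (3.64-fold). Mesendoderm genes lay at 0.02, or -0.04 when scaled by probes well above background on all arrays, with WNT3 9.92-fold higher and MESP1 3.11-fold lower.

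Fibroblast genes were not lower with LIN-41. The list's median was 0.24 (percentile 97.48), or 0.86 with spike-in scaling, with 12 of 38 members at least 2-fold higher and 2 lower. FN1, fibronectin, was 6.06-fold, FBLN1 5.09-fold, TAGLN 4.36-fold and COL1A1, a collagen, 3.93-fold higher. The TGF-beta list was higher by 0.35 and the CDK inhibitor and p53 list by 0.47 (1.08 with spike-in scaling), with the p53 targets BAX at 4.58-fold (0.74 and 2.20 on its probes), GDF15 at 3.74-fold and BBC3 at 3.23-fold.

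Among genes lower with LIN-41, EGR1, an immediate-early transcription factor whose messenger RNA is a reported LIN-41 target, was 3.32-fold lower. FOS (5.25-fold), FOSB (4.93-fold), DUSP1 (4.77-fold) and NR4A2 (3.37-fold), of the same immediate-early class, were lower as well. The immediate-early list had a median of -0.33 and the cell-cycle list of -0.12, and both turned above 0 with spike-in scaling. The list of reported LIN-41 targets had a median of -0.16 (percentile 4.88), with 2 of 16 genes at least 2-fold higher and 2 lower, and turned to 0.45 with spike-in scaling. The interferon list was lower by -0.73 (-0.11 with spike-in scaling), led by OAS1, at least 9.09-fold. The largest single values were MAOA (26.4-fold lower), HSD17B2 (10.5-fold), NPSR1 (9.78-fold), GK5 (9.76-fold), NTRK3 (9.64-fold, -0.61 on its other probe) and GPR15LG (9.53-fold). GK5 stood out on the OSK control array alone (-0.80, and -3.24 to -4.09 on the others). KRT6A was 3.60-fold lower and the neural list lay at -0.80 over 6 genes, which turned to 0.18 without a filter on dim genes.

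OSKM was compared with the OSK control across the same slides. Of 14185 genes, 1219 were at least 2-fold higher and 813 lower, against 2972 and 277 with spike-in scaling and 551 and 392 with normexp. The MYC and ribosome list was higher by a median of 1.01 (percentile 100), with 13 of 24 members at least 2-fold higher and 0 lower. MYBBP1A (3.92-fold), BOP1 (3.17-fold), FBL, the nucleolar methyltransferase fibrillarin (2.83-fold), and RRP9 (2.58-fold) led it. With spike-in scaling it was higher by 1.46. With LIN-41 this list lay at 0.13, or 0.75 with spike-in scaling. The MYC probe itself, which need not read the retroviral transcript, was 5.70-fold lower in OSKM than in the OSK control, and MYCN was 6.502-fold lower. KLF4 was 2.06-fold lower.

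Pluripotency genes were higher in OSKM by a median of 0.96, with 16 of 34 at least 2-fold higher and 1 lower. POU5F1 was 8.85-fold (again -0.27 on the other probe), NODAL 8.38-fold, LEFTY1 7.64-fold, LIN28B at least 6.43-fold and LIN28A 2.18-fold higher, and NANOG was 1.30-fold. The epithelial list was higher by 0.89, with PKP3, a desmosomal protein, 10.3-fold and CDH1 3.37-fold. ACTG2 (27.2-fold), FETUB (22.7-fold), ACTA1 (22.0-fold), EEF1A2 (19.4-fold), JPH1 (18.2-fold) and MT1G, a metallothionein (17.8-fold), were the leading higher genes. The stress list lay at 0.12, with ASNS, asparagine synthetase, 4.23-fold and HMOX1 4.15-fold higher. BAX, GDF15 and BBC3 were higher as with LIN-41, at 6.15-, 4.29- and 3.83-fold, with BAX at 1.08 and 2.62 on its probes.

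The leading lower genes in OSKM were SLC6A4, the serotonin transporter (21.9-fold), MGP, a matrix protein (12.98-fold), CD34 (8.97-fold), COL4A3 (8.67-fold), OLFM1 (8.35-fold) and NDNF (7.91-fold). The interferon list was lower by -0.92, with IFIT1 3.94-fold lower and IFIH1 at least 4.55-fold higher. The fibroblast list had a median of -0.27, the TGF-beta list of -0.26 and the cell-cycle list of -0.31, and all 3 turned above 0 with spike-in scaling. The let-7 target list lay at -0.06, or 0.40 with spike-in scaling. LHX1 was 7.91-fold lower. EGR1 differed by -0.25 and the immediate-early list by -0.13, and both turned above 0 with spike-in scaling.

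LIN-41 and OSKM shared a slide and were compared directly, with 778 genes at least 2-fold higher and 750 lower with LIN-41 of 14067 (1123 and 557 with spike-in scaling, 338 and 330 with normexp). Pluripotency genes were higher with LIN-41 by a median of 0.64 (percentile 100), with 12 of 38 at least 2-fold higher and 0 lower, including DPPA2 (3.89-fold), SOX2 (at least 3.53-fold), LIN28A (2.34-fold), LIN28B (2.13-fold) and NANOG (2.09-fold). Fibroblast genes were also higher, by 0.60, with SPARC at 3.58-fold and COL1A1 at 3.48-fold. Let-7 targets were higher by 0.45, among them MYC (4.67-fold), IGDCC3 (3.85-fold) and MYCN (3.51-fold). MYC lay at 1.77 with LIN-41, -0.45 in OSKM and 2.06 in the OSK control, and MYCN at 0.39, -1.42 and 1.28. Both probes thus read low in OSKM, and with LIN-41 neither lay above the OSK control. The MYC probe need not read the retroviral MYC given in OSKM, so it does not show total MYC there.

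The MYC and ribosome list was lower with LIN-41 than in OSKM by -0.83, with 0 of 24 members above 0 and 8 at least 2-fold lower, led by ODC1, the first enzyme of polyamine synthesis (3.36-fold), MYBBP1A (3.27-fold) and BOP1 (2.68-fold). EGR1 was 2.78-fold lower, while the reported LIN-41 targets as a list lay at 0.04. DCHS1 (11.3-fold), NGFR (11.2-fold), NTS (10.1-fold), SP5 (9.01-fold), GPR19 (8.28-fold) and CMKLR1 (7.77-fold) were the leading higher genes. SLC38A5, an amino acid transporter (34.8-fold), CD36, a fatty acid receptor (28.1-fold), SERPINB5 (17.1-fold), CAPN8 (13.1-fold), FETUB (12.8-fold) and WFDC11 (12.4-fold) were the leading lower genes. Keratinocyte genes were lower by -1.16 over 6 genes. The epithelial list lay at 0.09, with a mean of -0.13.

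**Figure D3:**
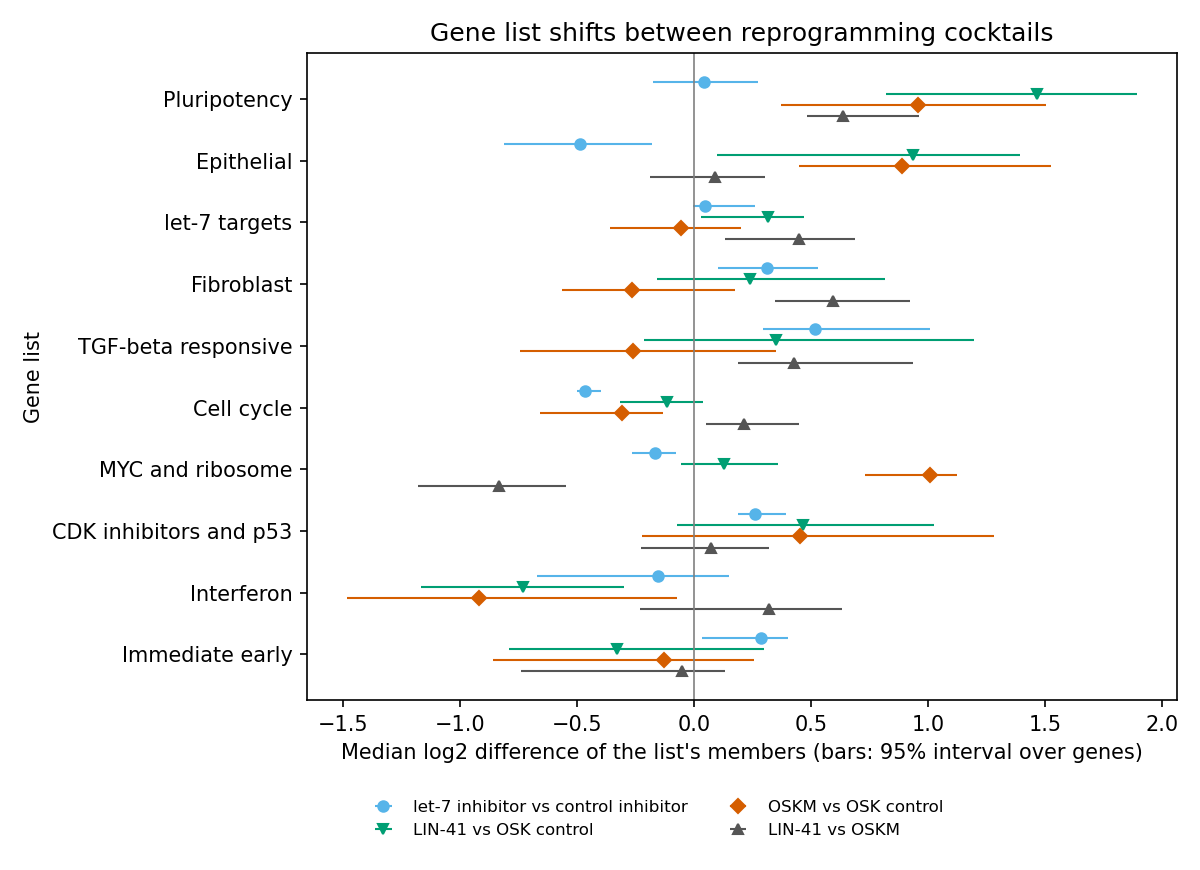
Median log2 difference of 10 gene lists in the 4 comparisons between cocktails, with bars for the 95% interval over genes. Pluripotency genes lie at 1.46 with LIN-41 and 0.96 in OSKM and the MYC and ribosome list at 1.01 in OSKM only. With spike-in scaling, the fibroblast, TGF-beta and cell-cycle medians of OSKM and the cell-cycle and immediate-early medians of LIN-41 turn above 0, as do the let-7 target and immediate-early medians of OSKM and the immediate-early median of LIN-41 against OSKM. The let-7 target and pluripotency medians of the let-7 inhibitor turn below 0.

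Differences from the OSK control correlated across 12788 genes, which are not independent replicates, at 0.57 between LIN-41 and OSKM, 0.50 between the let-7 inhibitor and LIN-41 and 0.16 between the let-7 inhibitor and OSKM. With no effect at all and spot noise only, the shared control array gave simulated correlations of 0.41, 0.46 and 0.43. The covariances were 0.2501, 0.103 and 0.0355, against 0.0078 simulated for each pair. LIN-41 and OSKM had 431 genes at least 2-fold higher in both (71.8 in independent lists of these sizes) and 285 lower in both (36.8). The let-7 inhibitor and LIN-41 had 95 higher (8.88) and 156 lower (10.2) in both. The single control array cannot be split, so part of each excess may come from it. LIN-41 and OSKM also share their slide, which the control array was not on, and lack the inhibitor transfection of the control.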

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

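No paired analysis was possible because each group had 1 array. No array could be left out for the same reason. The slide as a block left the 3 comparisons within a slide as they were, and it could not be estimated for the others. Signal over background limited the genes compared, since 66.2% to 75.4% of genes were well above background on an array. Over the alternatives, 63 of 1511 list medians had the opposite sign, 29 of them with spike-in scaling and 19 with no filter on dim genes. Of these, 10 belonged to lists that lay outside the central 95% of random lists. Apart from those 10, 1468 lay within the interval over genes, or had too few genes for one, and 33 lay outside it. Of the counts of genes at least 2-fold apart, 73 stayed within 1.5 times and 20 did not, and 14 of 6459 values for named genes had the opposite sign, 2 of them for genes at least 2-fold apart. Apart from those 2, 4592 values for named genes differed by less than the typical noise of spots and 1865 by more. Of the positions 46 were the same and 34 moved, and of the correlations 21 and 3. Where no cause is given, the cause was not tested.

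The 4-fold threshold by construction gave smaller counts, 64 for the let-7 inhibitor against its control, 302 for LIN-41 and 321 for OSKM against the OSK control, 237 for LIN-41 against OSKM, and 2369 for the OSK control, 2174 for the let-7 inhibitor, 2262 for LIN-41, 2379 for OSKM and 3821 for H1 against fibroblasts. With normexp and quantile normalization the between-cocktail counts were 104 for the let-7 inhibitor, 725 for LIN-41, 943 for OSKM and 668 for LIN-41 against OSKM. With no filter on dim genes they were 1281, 2759, 3231 and 2579. Keeping only genes well above background on both arrays gave 242 for the let-7 inhibitor. Spike-in scaling gave 3927 for LIN-41 and 3249 for OSKM.

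Spike-in scaling moved the median of all genes by -0.17 for the let-7 inhibitor, 0.62 for LIN-41 and 0.46 for OSKM against the OSK control, and 0.16 for LIN-41 against OSKM. Against fibroblasts it moved by 0.71 for LIN-41, 0.55 for OSKM and 0.87 for H1. Scaling by the array median moved it by -0.23 for H1. With spike-in scaling the genes higher and lower were 116 and 334 for the let-7 inhibitor (182 and 225 otherwise), 3708 and 219 for LIN-41 (1025 and 634), 2972 and 277 for OSKM (1219 and 813) and 1123 and 557 for LIN-41 against OSKM (778 and 750). Against fibroblasts they were 5917 and 1269 for LIN-41 (3050 and 2603), 5454 and 1570 for OSKM (3306 and 2733) and 7535 and 2028 for H1 (4260 and 3805). No other scaling moved such a split by over 10 percentage points, though with the array median fewer genes were higher (3560) than lower (4503) in H1.

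Among lists, spike-in scaling turned OSKM against the OSK control to 0.20 for TGF-beta genes, 0.15 for cell-cycle genes and 0.19 for fibroblast genes, and LIN-41 to 0.50 for cell-cycle, 0.29 for immediate-early and 0.10 for keratinocyte genes. It also moved the let-7 targets to 0.93 with LIN-41, 0.40 in OSKM and -0.12 with the let-7 inhibitor, and with LIN-41 the fibroblast list to 0.86 and the pluripotency list to 2.08. With no filter, mesendoderm genes turned to -0.0150 for LIN-41 against OSKM, and neural genes to 0.18 for LIN-41 against the OSK control, -0.41 for the OSK control and -0.28 for the let-7 inhibitor against fibroblasts. With the mean of a gene's probes, HMGA2 turned to -0.15 for LIN-41 and NCAM1 to -0.0477 for the let-7 inhibitor, both against fibroblasts.

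Positions are given for OSKM, LIN-41, the OSK control and the let-7 inhibitor in that order. On H1-high genes they were 55.6%, 61.4%, 33.4% and 25.5% with spike-in scaling, 55.5%, 60.6%, 46.9% and 43.4% with the array median, 43.4%, 43.8%, 26.8% and 26.6% with no filter, and 60.3%, 63.1%, 53.2% and 49.7% with genes well above background on both arrays. On fibroblast-high genes they were 53.8%, 44.5%, 62.3% and 64.9% with spike-in scaling, 51.9%, 48.6%, 48.5% and 47.5% with the array median, and 63.6%, 58.1%, 58.8% and 55.4% with normexp. OSKM was at 52.6% with quantile normalization, 59.7% with the 75th percentile of probes well above background and 52.5% with no filter. The let-7 inhibitor was at 49.5% with no filter and 49.8% with genes 8-fold apart, where LIN-41 was at 51.5%. The correlation between the let-7 inhibitor and OSKM was 0.12 with normexp and 0.32 with no filter, and that between LIN-41 and OSKM 0.56 with no filter.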

Other observations

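All gene sets and tests of this part were chosen after other results had been seen, except that the metallothionein, ATF4 and SRF lists were tested on members whose values had not been looked at. The tests on fibroblast-specific genes were given their final form after a first value was seen.

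A set of genes was far higher in the TRA-1-60 positive cells than in either end point, though not always low there, as IGF2 lay at 1.02 in H1. The end points shared a slide that held none of the TRA-1-60 positive arrays, so the slide cannot be told apart from this difference. On all 4 arrays 51 of 12788 genes were at least 16-fold above both fibroblasts and H1, and 23 to 53 under the other scalings. Over the 4 arrays and both end points the smallest fold was 175 for IGF2, 91.7 for RNASE1, 78.7 for PTHLH, a parathyroid hormone-like peptide, and 61.2 for SUSD2. Genes not well above background in either end point have only a bound, at least 387-fold for GPR15LG, 199-fold for SCARA5, 164-fold for KRT6A, 118-fold for SOST, an inhibitor of Wnt signalling, 56.8-fold for HOXD1 and 39.1-fold for SPRR2A, a gene of the cornified envelope of skin. In the opposite direction 2 of 12385 genes, NXPH4 (21.4-fold) and PTGIS (at least 16.4-fold, as it was dim on all 4 arrays), lay at least 16-fold below both, and 0 to 2 did under the other scalings. HOX genes, which record position along the body axis, had medians against fibroblasts of -0.96 in the OSK control, -0.97 with LIN-41 and -1.15 in OSKM (percentiles 0.81, 0.43 and 0.17), and -0.67 with the let-7 inhibitor, inside the central 95% of random lists (percentile 3.44). Members went both ways, with 2 or 3 of 14 or 15 at least 2-fold higher and 6 to 8 lower on each array, whereas in H1 the median was -5.44 and 14 of 14 were at least 2-fold lower.

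Metallothionein genes, which bind zinc and copper, were higher than in the OSK control by a median of 1.69 in OSKM (percentile 100 of random lists) and 1.99 with LIN-41, with 9 of 10 members at least 2-fold higher on each. Under the other scalings the OSKM median was 1.52 to 2.15. The OSK control lay below fibroblasts by -3.02. The member that was not higher, SLC30A1, is a zinc transporter and lay at -0.02 in OSKM and -0.10 with LIN-41. The remaining genes are near-identical copies of each other and of MT1G, which had been seen first. Their probes are therefore not independent, and neither the count nor the percentile is separate support for a difference of the whole family. Genes of the ATF4 and amino acid response were higher too, by 0.61 in OSKM and 0.49 with LIN-41 over 16 members, both at percentile 99.92, and by 0.52 to 1.07 and 0.32 to 1.11 under the other scalings. Against fibroblasts these members lay at -0.15 in OSKM and -0.14 with LIN-41, and at -0.86 in both the OSK control and the let-7 inhibitor. The difference may thus be a low value on the slide of the OSK control as much as a rise with MYC or LIN-41. Genes of the SRF and actin group were higher with LIN-41 (0.49, percentile 99.82) but not as a group in OSKM (0.08, percentile 37.71), although ACTA1 and ACTG2 were high on both, so a common difference of that group was not found. Within the slide the SRF and actin group was higher with LIN-41 than in OSKM by 0.55 (percentile 99.98), with an interval over the 11 genes of -0.27 to 0.91. The slide as the whole of the LIN-41 shift was not excluded, since that interval holds 0 and a lower group in OSKM would give the same difference. The other comparisons are across slides, so slide, handling and the inhibitor transfection of the OSK control stay open.

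The let-7 inhibitor array had lower epithelial and cell-cycle lists (-0.49 and -0.46) and a higher fibroblast list than its control. A larger share of unconverted fibroblasts would raise fibroblast-specific genes, and 170 such genes had a median of 0.19, a share of 0.373% that would shift the epithelial list by -0.0054. A scaling factor would move the lists alike, and they differed by 0.80. A scaling factor and fibroblasts like those of the GFP sample are therefore argued against for the lower lists. Unconverted cells that carry OSK were not measured, so the share does not cover them and they stay open. For the fibroblast list itself more fibroblasts could not be excluded, since the median was -0.0794 to 0.19 depending on the array the genes were picked against, and an effect of the inhibitor may stand behind both.

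The pluripotency list was higher on the LIN-41 and OSKM arrays than on the OSK control. The list lay at percentile 100 on both, among random lists matched on mean signal. That percentile is part of the pattern itself and not a separate test. The mean signal was taken over all arrays, so genes bright mainly in H1 were not matched on their brightness in this contrast. A shift of probes of like brightness could therefore not be excluded. Fewer fibroblasts would lower fibroblast-specific genes, and with LIN-41 their medians were 0.10 to 1.08 over the arrays they were picked against. The 1.08 came from genes picked against the OSK control, whose noise would raise it. Picked against H1, which is outside this contrast, 278 of 523 were higher, with a median of 0.10 beside 0.06 for all genes. These genes were thus not lower, but the contrast is across slides, so fewer fibroblasts were not excluded. More fibroblasts on that array stay open for its higher fibroblast genes. In OSKM the medians were -0.25 to 0.69 depending on the array picked against. The lowest lay above the -0.50 set for this explanation, but that limit was chosen after other results had been seen. Fewer fibroblasts in OSKM therefore stay open. Within the slide LIN-41 lay above OSKM by 0.64, a difference that handling common to both arrays would not give. Handling as the whole of the LIN-41 shift was still not excluded, since a lower list in OSKM would give that difference too. For the shift that both share (0.96 in OSKM), handling and the inhibitor transfection of the control could not be told apart from the cocktails. The slide holds no OSK control.

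EGR1 and other immediate-early genes were lower with LIN-41. EGR1 was only rank 5 from the lowest of 23 genes, and the others had a median of -0.31. Whether LIN-41 acted on EGR1 alone could not be decided from this, since stress and the slide stay open for the others. Stress from dissociation or sorting could not be told apart from an effect of LIN-41, since the 9 stress-responsive genes examined (median -0.68) are themselves immediate-early genes. EGR1, a gene named before the data were seen, was at -1.48 against OSKM on the same slide (-1.32 to -1.48 under the alternatives). The slide alone would not give that difference, but a higher EGR1 in OSKM would. As the whole difference of EGR1 from the OSK control, the slide was therefore not excluded. Within the slide FOS, FOSB, DUSP1 and NR4A2 differed from OSKM by -1.45, -1.83, -0.86 and 0.11. They were picked on the LIN-41 array, which this contrast shares, and in OSKM also lay below the OSK control, by a median of -1.17. For these genes the slide therefore stays open. It stays open for the list as a whole too, which lay at -0.0516 (percentile 34.28) within the slide, and against the OSK control it turned to 0.29 with spike-in scaling.

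The probes of HMGA2 differed with the let-7 inhibitor, at 1.86 for NM_003483 and at most 0.19 for NM_003484. One hypothesis is that let-7 acts on the first transcript, but it came from these same values, so they do not test it. The probes of POU5F1 differed too. The probe used by rule spanned 3.77 over the TRA-1-60 positive arrays, and the other 0.43, at 8.16 to 8.59 above fibroblasts, beside 8.95 in H1. The steadier probe may also read the retroviral transcript, but without its place on the transcript this could not be decided.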
